A study of Schizosaccharomyces pombe with 16 samples.

How the data were processed

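Total RNA of 4 fission yeast strains with analog-sensitive kinase alleles was measured on 16 Agilent 2-colour arrays. Per the labels, cells grew in rich medium at 32 °C to mid-log phase and received 30 µM 3-MB-PP1 in DMSO or DMSO alone; RNA was taken with acidic phenol and amplified and labelled with Cy3 or Cy5. Every array set treated against control RNA of 1 strain. Array replicates 1 and 2 carried treated RNA in Cy5 and replicates 3 and 4 in Cy3; replicates 1 and 3 were taken as the dye-swapped pair of biological replicate 1, and 2 and 4 as that of replicate 2.

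The deposited scanner tables hold, per the file headers, the intensity of each spot and of its local background in Cy3 and Cy5, made with Agilent Feature Extraction 9.5 per the submitters' processing notes, and not yet normalized. They also hold the deposited log10 ratio of Cy5 over Cy3 after the scanner software's own background subtraction and dye normalization, whose settings are not stated. The authors' values give a deposited log2 ratio per spot and array; how the authors normalized it is not stated. Set against the scanner's ratio through the spot number, its columns have slopes of 0.977 to 0.992 for bright probes and 0.560 to 0.680 for dim ones. At low signal they are thus smaller than the scanner's ratio, and which of them is closer to the true ratio is not known. All 16 columns are already turned to treated over control. The column medians of the authors' values lie between -0.0067 and 0.015. Whether it was centred by the authors on the median or on another quantity stays unknown.

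Of 45220 spots, 3469 were placeholders whose cells all hold the same value on every array and were left out, and 1417 were control spots. Of 40334 probes analysed, 16008 lie inside 5365 genes and 24326 between genes, by the annotation in the tables. Background was corrected with normexp (offset 50) on all spots, ratios were normalized within each array with loess in which controls had weight 0, spots marked as non-uniform or population outliers by the scanner software were left out, and all ratios were turned to treated over control. Spots of a probe were averaged, then the 2 arrays of each dye-swapped pair, which cancels the dye effect and leaves 8 values. Probes well above background in either channel on at least 4 of 16 arrays were kept, and a gene is the mean of its probes inside the gene (median 3 probes). This left 5311 genes, 355 of them non-coding, with 54 filtered out; 54 genes had probes on both strands. Names came from the tables and from the reference gene annotation of assembly ASM294v3, used for names and gene types only: 5166 identifiers matched by locus tag, 22 by synonym and 123 not at all, and those kept the name in the tables. Neighbours of probes between genes came from the annotation and probe positions in the tables. The genome build of the probe positions is not stated, so no coordinates are given.

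The model in limma had 1 mean per strain over the 8 values, with moderated variances (4 residual and 7.84 prior degrees of freedom) and 2-sided tests, adjusted by Benjamini-Hochberg over 5311 genes and called at adjusted p 0.05. The 8 comparisons were treated over control in each strain and 4 differences between strains' responses. Calls of at least 2-fold also have a log2 ratio of at least 1 in size. The p-values measure only the spread between these samples, which was small: the typical SD between biological replicates was 0.0209 to 0.0344 on the log2 scale, and replicate values correlated at 0.982 to 0.994 across genes. Of 30 gene lists from textbook knowledge, the 29 with at least 5 measured members were tested with camera (limma) with a preset correlation of 0.01 and again with an estimated one, and adjusted within each comparison. The list of Tf2 retrotransposons had 3 measured members and was not tested, and the results of 1 tested list are not given. The design, the lists, the rule for named genes and all but 1 of the alternative settings for genes were fixed before the data were examined. That rule takes, per strain, the 10 largest rises and 10 largest falls among called genes with the same sign on all 4 arrays, leaving out non-coding features and pseudogenes; per difference, the 5 largest in each direction, with the same features left out, whose replicates did not overlap between the strains; per called list, the 4 members with the smallest p in the list's direction; and always mcs6, cdk9, pch1, mcs2, csk1, rpb1, ste11, fbp1, ura4, eng1 and cdc18. Control levels come from the control channel. Background-corrected log2 signals of both channels of all arrays were quantile-normalized together, without control spots. Outlier spots were then left out, and probes, swapped pairs and genes were averaged as for the ratios.

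Alternatives were median centring, no background correction, the scanner software's log ratio, the authors' values, no filter or a stricter filter on dim probes, the brightest probe per gene, arrays as samples with a dye term and random block, only the strains compared, a replicate block, each replicate left out, and an estimated correlation for the lists. A further one, mcs6-as2 and the double mutant counted as 1 replicate each, was added after seeing the data. On simulated data over 5311 genes for each of the 8 comparisons, 0% to 14% of genes changed by 0.1 on the log2 scale were recovered, 72% to 100% at 0.25, 94% to 100% at 0.5 and 100% at 1. Between 3.55% and 6.90% of the simulated calls were false. The list made to change was called in 8 of 8 comparisons, and 0 of 160 unchanged lists were. The simulation changed 50 genes at each size, let genes vary independently and made the unchanged lists from random genes. It therefore does not test calls where most genes change, or lists whose members vary together. Computations used R 4.3.3 with limma 3.58.1, jsonlite 2.0.0 and the package data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for plots.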

Results

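Transcript levels of fission yeast, Schizosaccharomyces pombe, were compared on 16 2-colour oligonucleotide arrays between cells given the kinase inhibitor 3-MB-PP1 and cells given its solvent, DMSO. Each of the 4 strains carries at least 1 analog-sensitive (as) kinase allele, in which an enlarged ATP pocket admits bulky ATP-competitive compounds such as 3-MB-PP1. Mcs6 is the fission yeast Cdk7, which phosphorylates other cyclin-dependent kinases as a CDK-activating kinase and also the C-terminal domain of RNA polymerase II. Cdk9, with its cyclin Pch1, phosphorylates that domain and the elongation factor Spt5. The strains were cdk9-as, mcs6-as2, mcs6-as2 in a CAK1 background, and mcs6-as2 cdk9-as with the same CAK1 label, called the double mutant here. CAK1 is the name of the CDK-activating kinase gene of budding yeast; the labels do not say what the CAK1 background holds. The genotype label of the mcs6-as2 strain says mcs6-as, and it was read here as the allele named mcs6-as2 elsewhere. Each strain was taken to have 2 biological replicates, and each replicate was hybridised on a dye-swapped pair of arrays with treated and control RNA of the same strain on every array. In mcs6-as2 and the double mutant the difference between the replicates did not recur between dye orientations (r = -0.069 and 0.022 across genes), so whether these are separate cultures is not shown. Between 62.0% and 76.1% of probe spots were well above background in a channel, 0 spots were saturated, and 5311 genes entered the tests. The number of arrays limits the precision, no strain without an as allele was measured, and the labels give no treatment time.

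The kinase genes themselves were read first, since they check the strain labels. In DMSO-treated cells, cdk9 mRNA stood at 7.92 ± 0.019 (SD, n = 2; normalized log2 signal) in cdk9-as, against 9.29 ± 0.014 in mcs6-as2, 9.34 ± 0.0019 in mcs6-as2 CAK1 and 9.48 ± 0.044 in the double mutant, which by its label carries the same cdk9-as allele. The mcs6 control level lay between 9.22 in mcs6-as2 and 9.52 in cdk9-as. The marker gene ura4, which the CAK1 label names, was not well above background on any of the 12 control spots of any strain, and was not tested. Its control level was 6.09 in mcs6-as2 CAK1 and 6.21 in the double mutant, against 6.13 in mcs6-as2 and 6.14 in cdk9-as. It thus did not set the CAK1 strains apart and gave their label no support. The adenine biosynthesis gene ade6 stood at 10.59 in mcs6-as2 CAK1 and at 11.53 to 11.65 in the other strains.

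**Figure D1:**
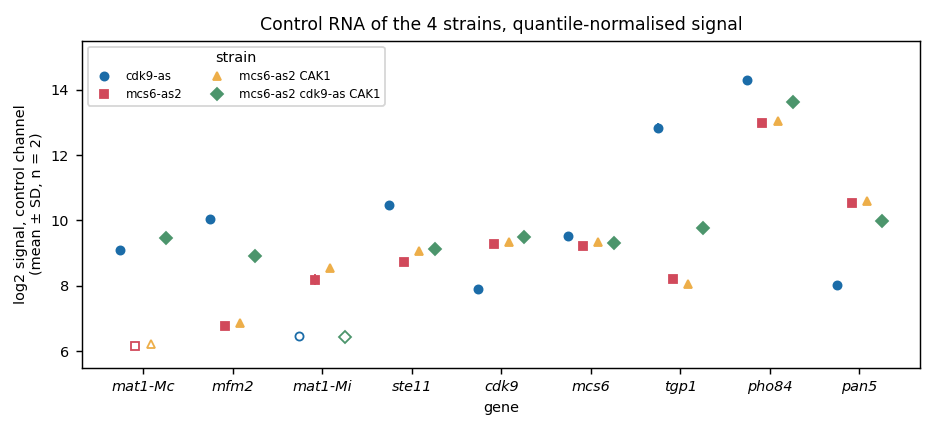
Normalized log2 signal of 9 genes in the DMSO control channel of each strain (points, mean of 2 biological replicates; bars, SD), with open symbols where a gene was not well above background on all 4 control arrays. The cdk9 gene reads 7.92 in cdk9-as and 9.29 to 9.48 in the other strains, and the genes other than cdk9, mcs6 and ste11 were chosen after their values were seen.

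In cdk9-as cells, where the compound is directed at Cdk9, the genes that rose most included a chaperone, a transporter and a glycolytic enzyme, and those that fell most included both subunits of a copper transporter. Non-coding features and pseudogenes were tested and counted, but the largest changes below are named without them. The largest rises on the log2 scale were those of SPBPB2B2.18 (4.12), SPAC513.07 (3.58) and SPCC584.16c (3.19), followed by fub2 (3.00), the ABC transporter gene bfr1 (2.80), SPAPB24D3.07c (2.71), SPAC27D7.11c (2.63), SPBPB2B2.06c (2.62), the small heat shock protein gene hsp16 (2.55) and the glyceraldehyde-3-phosphate dehydrogenase gene gpd3 (2.43). The largest falls were those of ctr4 (-3.18) and ctr5 (-2.83), whose products form the high-affinity copper transporter, and of the heat shock gene hsp9 (-2.88). The carbonic anhydrase gene nce103 (-2.25), the lipase gene ptl2 (-2.23), the ribosomal protein gene rpl1603 (-2.20), SPBC887.17 (-2.20), SPBPB8B6.05c (-2.03), SPAC977.12 (-1.94) and the biotin transporter gene vht1 (-1.83) also fell. These 20 changes had standard errors of 0.025 to 0.117 and adjusted p of at most 6.14e-11 (limma, n = 2). The widest was that of ctr4, whose replicates had an SD of 0.55. The fub2 control signal in cdk9-as was dim (6.465) and well above background on 2 of 4 control arrays, so the size of its rise there is less sure.

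Members of gene lists named below are those with the smallest p in the list's direction, not the largest changes. Among the lists, 30 of 33 proteasome genes rose in cdk9-as and 3 fell (median log2 ratio 0.54), with pre4 at 1.07, rpn3 at 0.96, pre3 at 1.04 and rpn1302 at 0.86. Of 20 heat shock and chaperone genes 16 rose and 2 fell (median 0.71), including hsp16, psi1 (1.80), the Hsp70 gene ssa1 (2.13) and hsp104 (2.07). Of 16 glycolysis genes 14 rose and 1 fell (median 0.69), among them gpd3, the enolase gene eno101 (0.94), pgk1 (0.93) and the alcohol dehydrogenase gene adh1 (1.13). The set test (camera, preset correlation) gave adjusted p of 8.69e-08, 7.25e-05 and 1.49e-05 for these lists, and each had adjusted p = 0.337 with an estimated correlation. Ribosomal protein genes fell, 126 of 139 (6 rose; median -0.51; adjusted p 1.70e-12, and adjusted p = 0.337 with an estimated correlation), as rpl1603, rps1902 (-1.01), rpl2502 (-1.21) and rpl702 (-0.99) did. Of 80 ribosome biogenesis genes 62 fell and 7 rose (median -0.36; adjusted p 4.70e-06, and adjusted p = 0.619 with an estimated correlation), among them rrp8 (-1.12), rlp24 (-1.13), tsr2 (-0.93) and nop12 (-0.73). RNA polymerase I and III subunit genes fell in 15 of 20 cases and rose in 0 (median -0.52), with rpa12 at -0.81, rpc40 at -0.99, rpc19 at -0.88 and rpa43 at -0.81. Of 11 histone genes 10 rose and 1 fell (median 0.46), including htb1 (1.13), hta2 (0.67), hhf1 (0.54) and hta1 (0.63). Of 43 respiratory chain and ATP synthase genes 25 rose and 12 fell (median 0.19), including atp4 (0.84), atp3 (0.68), sdh3 (0.93) and atp14 (0.68). Adjusted p for the polymerase, histone and respiratory lists was 0.00125, 0.00189 and 0.0275, and for each adjusted p = 0.422 with an estimated correlation; the respiratory call was also lost with median centring (adjusted p 0.0565). Adjusted over the list alone, these counts were the same. Among genes fixed for every strain, ste11, which encodes the transcription factor for mating genes, fell by 1.53. The genes mcs6 (-0.41), cdk9 (-0.41), eng1 (-0.38; septum degradation), csk1 (-0.28; the kinase that activates Mcs6) and fbp1 (-0.27; gluconeogenesis) fell. The Mcs6 cyclin gene mcs2 stood at 0.13, which passed the test but turned to -0.015 with median centring of the arrays and lost the call in the scanner software's log ratio (adjusted p 0.0544). The replication gene cdc18 (-0.049, adjusted p 0.102), pch1 (-0.022, adjusted p 0.494) and the polymerase II gene rpb1 (0.017, adjusted p 0.576) did not pass the test. The fall of cdc18 passed with median centring, without background correction, in the scanner software's log ratio, in the authors' values and with the brightest probe (-0.064 to -0.18; adjusted p 3.86e-05 to 0.0354), and that of pch1 in the scanner software's log ratio (-0.26, adjusted p 0.00366). With the brightest probe pch1 turned to 0.097 and rpb1 to -0.10, and both passed the test (adjusted p 0.0222 and 0.00666), so the direction of these genes is open.

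In all, 4561 of 5311 genes passed adjusted p 0.05 in cdk9-as (limma), 2049 of them higher and 2512 lower, of which 114 and 94 changed at least 2-fold. With median centring in place of loess the split was 1301 higher and 2738 lower, and 83 and 169 at 2-fold; the scanner software's log ratio put 170 higher and 335 lower at 2-fold. Every array is scaled on its own, so a change shared by all transcripts is not measured.

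In mcs6-as2 cells, where the compound is directed at Mcs6, the largest rises belonged to fub2 (4.41), SPBPB2B2.18 (4.24) and hsp16 (3.74), and next to the Tf2 retrotransposon genes Tf2-2 (3.69), Tf2-11 (3.65) and Tf2-1 (3.61). SPAPB24D3.07c (3.12), SPCC1235.01 (2.75), cmt1 (2.64) and SPAC513.07 (2.48) completed the 10 largest. Both copper transporter genes fell, ctr4 (-2.70) and ctr5 (-2.26), as did nce103 (-2.37), SPBC887.17 (-2.40), the amino acid transporter gene aat1 (-2.38), SPBPB10D8.01 (-2.17), pan5 (-2.10), SPBC359.01 (-2.09) and the fluoride exporter genes fex1 (-1.79) and fex2 (-1.77). Standard errors of these 20 values were 0.0245 to 0.117 and adjusted p at most 3.78e-10 (limma, n = 2). Of the genes with the largest changes in any strain, Tf2-1, SPBC359.01, fex1, fex2 and SPAC977.12 had probes on both strands, and all probes of each moved the same way.

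Of 80 ribosome biogenesis genes 73 fell in mcs6-as2 and 3 rose (median -0.43), among them rrp15 (-1.20), rlp24 (-1.08), noc3 (-0.89) and rrp36 (-0.72); adjusted p was 1.52e-10, and adjusted p = 0.448 with an estimated correlation. Of 139 ribosomal protein genes 124 fell and 6 rose adjusted over the list alone, with 1 fewer falling over all genes (median -0.30), with rps1701 at -1.25, rps1902 at -1.06, rps1401 at -1.0 and rpl1602 at -1.04. RNA polymerase I and III subunits followed, 19 of 20 lower and 0 higher (median -0.40), including rpa34 (-1.04), rpa12 (-0.82), nuc1 (-0.78), which encodes the largest polymerase I subunit, and rpc25 (-0.81). Proteasome genes rose in 28 of 33 cases and fell in 3 (median 0.38), with pre1 (0.70), rpn3 (0.66), pre9 (0.66) and scl1 (0.60) among them. The 3 lists gave adjusted p of 1.52e-10, 5.82e-05 and 1.10e-06, and for each adjusted p = 0.379 with an estimated correlation. Of 20 heat shock and chaperone genes 13 rose and 5 fell (median 0.23), including hsp16, the mitochondrial chaperone gene hsp78 (1.30), sti1 (1.36) and psi1 (1.21). Of 34 core stress response genes 19 rose and 11 fell (median 0.18), with hsp16, the glutathione S-transferase gene gst2 (2.36), obr1 (1.78) and zta1 (1.42) among the former. Both had adjusted p 0.0118, and adjusted p = 0.379 with an estimated correlation. Iron and copper regulated genes fell in 20 of 26 cases and rose in 4 (median -0.36; adjusted p 0.0118, and adjusted p = 0.502 with an estimated correlation), with ctr5, adh4 (-1.20), the iron-responsive repressor gene fep1 (-0.74) and the zinc transporter gene zrt1 (-0.79) among the former. With the adjustment over the list alone, 20 stress genes rose and 12 fell, and the counts of the other lists were the same. Of the genes fixed for every strain, eng1 (-0.85), ste11 (-0.57), pch1 (-0.40), csk1 (-0.32), rpb1 (-0.12) and, with adjusted p 0.0202, mcs6 (-0.087) fell, and fbp1 (0.35) rose. Values for cdc18 (0.096) and mcs2 (0.085) passed the test but turned to -0.0036 and -0.014 in the scanner software's log ratio, and cdk9 (0.017, adjusted p 0.557), which did not pass, turned to -0.12 there and passed (adjusted p 0.00582). Calls of cdc18, mcs6 and mcs2 were lost with median centring (adjusted p 0.0830, 0.245 and 0.169) and with mcs6-as2 and the double mutant counted as 1 replicate each, a setting chosen after seeing the data (0.0665, 0.128 and 0.117), that of mcs6 also with the brightest probe (0.0845). Leaving out replicate 1 ended those of cdc18 and mcs6 (0.189 and 0.303), and leaving out replicate 2 those of mcs2 and rpb1 (0.186 and 0.0706; rpb1 at -0.078).

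The mcs6-as2 test called 4348 genes (limma), 1872 higher and 2476 lower, with 102 higher and 95 lower at 2-fold or more. The scanner software's log ratio put 167 higher and 328 lower at 2-fold.

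**Figure D2:**
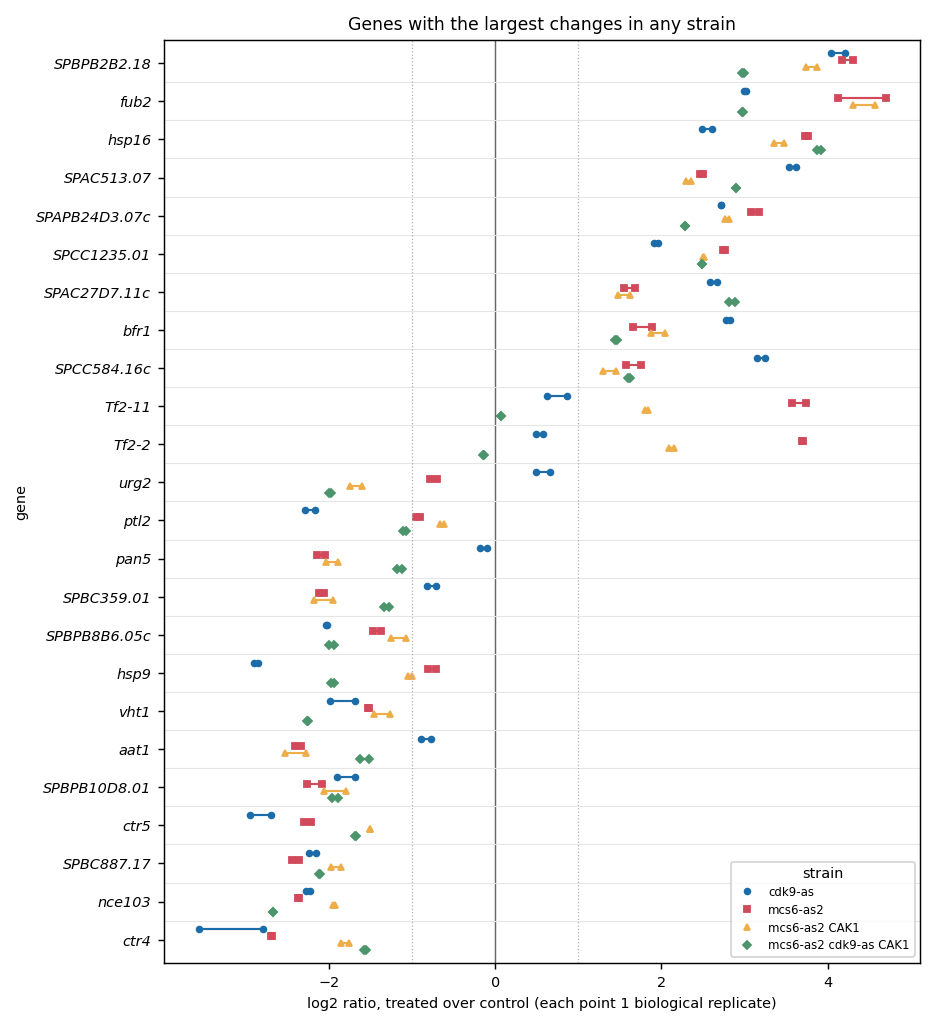
Log2 ratio of treated over control RNA for 24 genes in the 4 strains, with each point 1 biological replicate and dotted lines at a 2-fold change. The gene hsp16 reads 2.55 to 3.89 in all 4 strains, while Tf2-2 reads 3.69 in mcs6-as2 and -0.14 in the double mutant.

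In mcs6-as2 CAK1 cells, with the mcs6-as2 allele in the CAK1 background, the same top gene, fub2 (4.44), was followed by SPBPB2B2.18 (3.81), hsp16 (3.41), SPAPB24D3.07c (2.79) and SPCC1235.01 (2.50). Then came gpd3 (2.35), SPAC513.07 (2.32), cmt1 (2.19), Tf2-2 (2.12) and SPAC27D7.09c (2.11). The amino acid transporter gene aat1 fell most (-2.40), before SPBC359.01 (-2.07), pan5 (-1.97), nce103 (-1.94), SPBPB10D8.01 (-1.93), SPBC887.17 (-1.92), SPAC5H10.07 (-1.82), ctr4 (-1.80), SPAC26F1.11 (-1.68) and the uracil-regulated gene urg2 (-1.68). Standard errors were 0.0245 to 0.117 and adjusted p at most 2.05e-08 for these 20 genes (limma, n = 2).

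Ribosomal protein genes fell in 118 of 139 cases and rose in 5 in mcs6-as2 CAK1 (median -0.25), among them rps1701 (-1.15), rpl1602 (-1.01), rps1702 (-0.98) and rps1401 (-0.94). Proteasome genes rose in 27 of 33 cases and fell in 3 (median 0.37), with pre1 at 0.64, rpn3 at 0.59, pre9 at 0.58 and rpn1302 at 0.50. Heat shock and chaperone genes rose in 11 of 20 cases and fell in 4 (median 0.21), including hsp16, hsp78 (1.23), sti1 (1.29) and psi1 (1.17). Adjusted p for the 3 lists was 8.59e-10, 2.06e-06 and 0.00762, and for each adjusted p = 0.388 with an estimated correlation. Ribosome biogenesis genes fell in 70 of 80 cases and rose in 6 (median -0.28), for example rrp15 (-1.0), rlp24 (-0.92), noc3 (-0.81) and dbp9 (-0.74). Of 26 iron and copper regulated genes 19 fell and 5 rose (median -0.28), including adh4 (-1.08), ctr5 (-1.51), fep1 (-0.62) and the siderophore transporter gene str1 (-1.33). Of 25 genes for nitrogen starvation and amino acid uptake 16 fell and 6 rose (median -0.42), including aat1, the ammonium transporter gene amt1 (-1.59), the uracil permease gene fur4 (-1.07) and urg2. These 3 lists had adjusted p 9.26e-08, 0.0259 and 0.0326, and for each adjusted p = 0.563 with an estimated correlation. RNA polymerase I and III subunits fell in 18 of 20 cases and rose in 1 (median -0.31; adjusted p 9.07e-04, and adjusted p = 0.466 with an estimated correlation), with rpa34 (-0.82), nuc1 (-0.63), rpc25 (-0.72) and rpa12 (-0.59). Of 56 amino acid biosynthesis genes 40 fell and 10 rose (median -0.18; adjusted p 0.00762, and adjusted p = 0.682 with an estimated correlation), among them met14 (-1.06), hom2 (-1.12), ilv5 (-0.81) and ilv3 (-0.68). The counts adjusted over the list alone were the same. Among genes fixed for every strain, ste11 (-0.66), eng1 (-0.65), pch1 (-0.29), csk1 (-0.26) and rpb1 (-0.15) fell. The genes fbp1 (0.14), mcs2 (0.13) and cdc18 (0.10) rose. The kinase genes mcs6 (-0.043, adjusted p 0.221) and cdk9 (0.021, adjusted p 0.461) did not pass the test, but in the scanner software's log ratio both passed as lower (-0.10 and -0.083; adjusted p 0.0351 and 0.0325), and with the brightest probe cdk9 passed as higher (0.10, adjusted p 0.00756).

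This strain had 4257 calls (limma), 1844 higher and 2413 lower, and 71 higher and 75 lower at 2-fold or more. The scanner software's log ratio ended the iron and copper and the nitrogen list calls (adjusted p 0.0878 and 0.0976), and those of cdc18 and mcs2 (0.187 and 0.228), which median centring ended too (0.188 and 0.102). The scanner software's log ratio gave 1409 higher and 2830 lower, and 122 and 256 at 2-fold.

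In the double mutant, which carries both as alleles, hsp16 rose most (3.89), before SPBPB2B2.18 (2.98), fub2 (2.97), SPAC513.07 (2.90), SPAC27D7.11c (2.85), SPAC27D7.10c (2.62), SPCC1235.01 (2.49), SPAPB24D3.07c (2.29), gpd3 (2.20) and SPBC1685.12c (2.05). The largest falls were those of nce103 (-2.67), vht1 (-2.25), SPBC887.17 (-2.12), urg2 (-1.99), SPBPB8B6.05c (-1.98), hsp9 (-1.96), SPBPB10D8.01 (-1.93), SPAC977.12 (-1.93), SPCPB1C11.03 (-1.91) and rpl1603 (-1.88). These 20 values had standard errors of 0.0245 to 0.0958 and adjusted p of at most 3.1e-11 (limma, n = 2).

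Glycolysis genes rose in 14 of 16 cases and fell in 2 in the double mutant (median 0.79), with gpd3, pgk1 (1.31), eno101 (1.13) and the hexokinase gene hxk2 (0.96) among the former. Proteasome genes rose in 30 of 33 cases and fell in 2 (median 0.42), with rpn3 (0.87), pre3 (0.99), pre9 (0.75) and pre4 (0.73). Heat shock and chaperone genes rose in 15 of 20 cases and fell in 4 (median 0.29), with hsp16, ssa1 (1.89), hsp104 (1.87) and psi1 (1.13). Ribosomal protein genes fell in 120 of 139 cases and rose in 12 (median -0.46), with rpl1603, rpl1902 (-0.80), rps1902 (-0.84) and rpl2502 (-1.0). Adjusted p for these 4 lists was 1.20e-04, 4.41e-08, 6.11e-04 and 1.48e-11, and for each adjusted p = 0.343 with an estimated correlation. Histone genes rose in 9 of 11 cases and fell in 1 (median 0.60), with htb1 (1.21), hta2 (0.84), hta1 (0.96) and hhf1 (0.75). RNA polymerase I and III subunits fell in 16 of 20 cases and rose in 2 (median -0.31), with rpa43 (-0.86), rpc40 (-0.77), rpa12 (-0.59) and rpc25 (-0.65). Of 25 genes for nitrogen starvation and amino acid uptake 18 fell and 5 rose (median -0.64), including urg2, the malate permease gene mae1 (-1.36), the peptide transporter gene ptr2 (-1.14) and fur4 (-0.91). Of 89 genes on cosmids at chromosome ends 59 fell and 20 rose (median -0.26), including SPAC977.12, SPBPB10D8.05c (-1.53), SPCC569.03 (-1.45) and SPCC569.05c (-1.09). The 4 lists gave adjusted p of 6.11e-04, 0.0216, 0.0114 and 0.0216, and for each adjusted p = 0.504 with an estimated correlation; with median centring the list of chromosome ends had adjusted p 0.392. Of 80 ribosome biogenesis genes 62 fell and 8 rose (median -0.25; adjusted p 1.20e-04, and adjusted p = 0.534 with an estimated correlation), with rrp8 (-1.24), rlp7 (-0.75), nop12 (-0.75) and rrp15 (-0.81). Of 56 amino acid biosynthesis genes 37 fell and 14 rose (median -0.26; adjusted p 0.0111, and adjusted p = 0.596 with an estimated correlation), with leu2 (-1.60), met17 (-1.14), met14 (-0.88) and ilv3 (-0.81). These counts did not change when adjusted over the list alone. Of the genes fixed for every strain, ste11 (-1.04), mcs6 (-0.28), cdk9 (-0.24), fbp1 (-0.17), eng1 (-0.17), csk1 (-0.12) and rpb1 (-0.10) fell, and mcs2 (0.31), cdc18 (0.13) and pch1 (0.11) rose. The calls of cdc18 and pch1 were lost with median centring (adjusted p 0.730 and 0.933) and in the scanner software's log ratio (0.120 and 0.298), that of pch1 also without replicate 1 (0.177), and that of fbp1 with the brightest probe (-0.056, adjusted p 0.163). Leaving out replicate 2 ended those of csk1 (-0.070, adjusted p 0.148) and rpb1 (-0.081, adjusted p 0.105), the latter being also lost with mcs6-as2 and the double mutant counted as 1 replicate each (0.0560).

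The test called 4438 genes in the double mutant (limma), 1975 higher and 2463 lower, with 71 and 94 at 2-fold or more. Median centring gave 1038 higher and 2804 lower, and 44 and 198 at 2-fold, and the scanner software's log ratio 147 and 321 at 2-fold. In none of the strains or differences did a called list reverse under median centring, the scanner software's log ratio, the authors' values or uncorrected signals, which moved the median of all genes by at most -0.115, -0.121, -0.0034 and -0.0080.

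**Figure D3:**
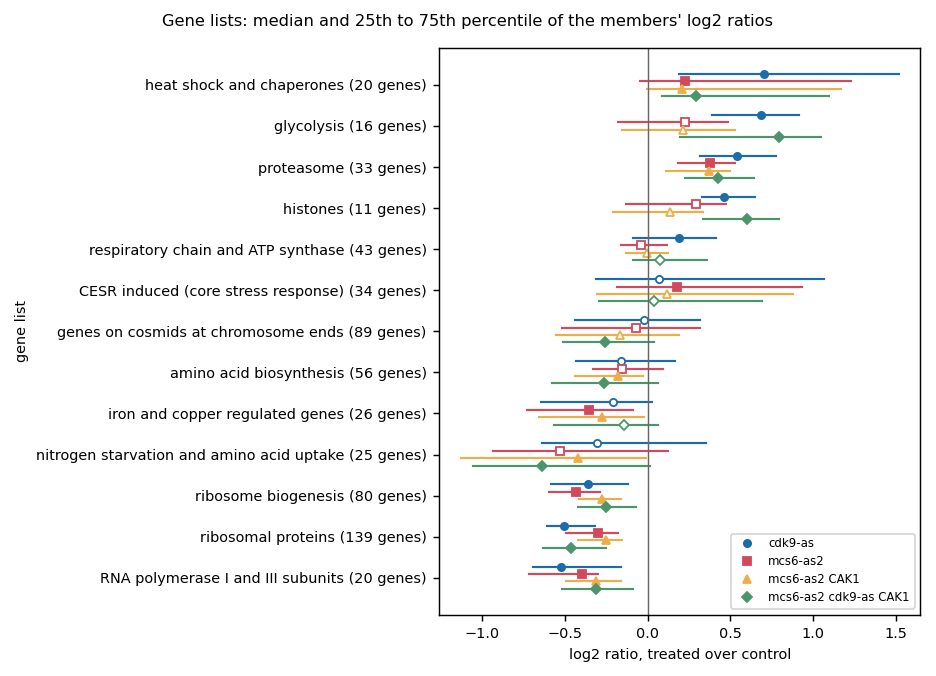
Log2 ratio of treated over control RNA for the members of 13 gene lists in each strain (points, median; bars, 25th to 75th percentile), filled where the list passed the set test with its preset correlation. Proteasome genes lie above 0 with medians of 0.37 to 0.54, and ribosomal protein genes below 0 with medians of -0.51 to -0.25, in all 4 strains.

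Several lists close to the kinases' known roles passed the set test in none of the strains. RNA polymerase II subunits, C-terminal domain kinases and elongation factors (51 genes) had adjusted p of 0.294, 0.866, 0.882 and 0.0993 in cdk9-as, mcs6-as2, mcs6-as2 CAK1 and the double mutant, with medians of 0.042, -0.016, -0.024 and 0.091. In the same order Mediator genes (23) had adjusted p of 0.236, 0.347, 0.516 and 0.68, and MBF targets (24) 0.656, 0.511, 0.408 and 0.703. Of 32 mating genes 22 fell and 6 rose in cdk9-as, with adjusted p 0.0908, and in the other strains adjusted p was 0.448, 0.529 and 0.703.

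A core of genes changed in every strain: 30 were at least 2-fold higher in all 4, 27 of them protein-coding, and 19 were at least 2-fold lower. The higher ones included SPBPB2B2.18, fub2 and hsp16, whose smallest log2 ratios over the strains were 2.98, 2.97 and 2.55, as well as SPAC513.07 (2.32), SPAPB24D3.07c (2.29), gpd3 (2.20), bfr1 (1.45), hsp104 (1.45), ssa1 (1.16), psi1 (1.13) and obr1 (1.08). With median centring 25 of the 30 higher and all 19 lower genes stayed past 2-fold in every strain; psi1 and obr1 were among those that did not (0.92 and 0.76 in the double mutant). The scanner software's log ratio put 54 higher and 83 lower in all 4 strains, and the brightest probe 42 and 30, so the size of the core and its balance depend on the processing. The lower ones included nce103, SPBC887.17, ctr4, ctr5, fex1, fex2, vht1 and rpl1603, each at least 2-fold lower in every strain. Fold changes of single genes correlated most between mcs6-as2 and mcs6-as2 CAK1 (Pearson r = 0.964, Spearman rho = 0.960, across 5311 genes, which are not independent replicates). They came next between cdk9-as and the double mutant (0.864 and 0.855), and least between cdk9-as and either mcs6 strain (0.632 and 0.631 by Pearson; 0.568 by Spearman). The double mutant correlated at 0.702 and 0.641 with mcs6-as2 CAK1 and at 0.657 and 0.606 with mcs6-as2. Of the 2-fold calls, cdk9-as and mcs6-as2 shared 50 higher and 31 lower genes, where independent lists would share 2.19 and 1.68, and mcs6-as2 and mcs6-as2 CAK1 shared 69 and 63, against 1.36 and 1.34. The double mutant shared 56 higher and 50 lower genes with cdk9-as, against 1.52 and 1.66 for independent lists. All 12 overlaps of strain pairs by direction exceeded independence, with adjusted p of at most 1.89e-31 (Fisher's exact test, 2-sided).

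**Figure D4:**
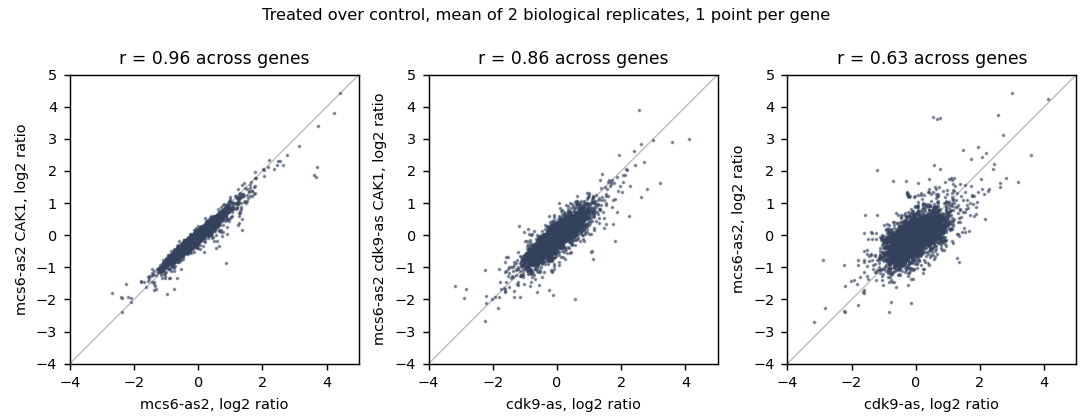
Log2 ratios of treated over control RNA of single genes in 3 pairs of strains, 1 point per gene. The points follow the diagonal most closely for mcs6-as2 against mcs6-as2 CAK1 (r = 0.96), then for cdk9-as against the double mutant (r = 0.86), and least for cdk9-as against mcs6-as2 (r = 0.63).

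The series asks how Mcs6 acts through its CDK-activating and its polymerase-directed activity, and the mcs6-as2 strains with and without the CAK1 label were compared with this in view. The pair cannot by itself separate these activities, since the labels leave the background open, the allele was only read as the same, and the controls also differed in ade6 (10.59 and 11.65). The retrotransposon genes responded less in the CAK1 background, with differences of -1.83 for Tf2-11, -1.72 for Tf2-1 and -1.57 for Tf2-2. SPCC70.08c did too (-1.21), and SPAC186.06 differed by -1.74, with log2 ratios of 0.87 in mcs6-as2 and -0.87 in mcs6-as2 CAK1. The falls of ctr4 and ctr5 were smaller (differences of 0.89 and 0.75), and so were those of SPBC887.17 (0.48), nce103 (0.43) and of the mRNA export gene mlo3 (0.39). The largest adjusted p of these 10 genes was 0.00397 (limma, n = 2 per strain). Control levels were lower in mcs6-as2 CAK1 than in mcs6-as2 for SPCC70.08c (9.42 and 11.01), SPAC186.06 (7.69 and 8.53) and Tf2-1 (9.22 and 9.95). They were also lower for Tf2-11 (9.64 and 10.38) and nce103 (13.76 and 14.23), and higher for SPBC887.17 (11.54 and 11.22). For these genes the response cannot be read apart from the starting level. Control levels of Tf2-2, ctr4, ctr5 and mlo3 did not differ by the test (adjusted p 0.434 to 0.970, limma). Ribosome biogenesis genes fell less in the CAK1 background: 35 of 80 differed upward and 0 downward (median difference 0.13), and RNA polymerase I and III subunits did so in 11 of 20 cases and 0 (median 0.14). Genes on cosmids at chromosome ends were lower in the CAK1 strain's response in 24 of 89 cases and higher in 3 (median -0.084), histones lower in 3 of 11 and higher in 0 (median -0.10), and nitrogen genes lower in 9 of 25 and higher in 4 (median -0.11). These lists had adjusted p 2.23e-16, 2.49e-07, 4.53e-06, 0.00158 and 0.00122, and each had adjusted p = 0.412 with an estimated correlation. Core stress genes were lower in 13 of 34 cases and higher in 0 (median -0.091; adjusted p 2.62e-06, and adjusted p = 0.117 with an estimated correlation). Ribosomal protein genes were higher in 9 of 139 cases and lower in 0 (median 0.046), and glucose-repressed genes lower in 5 of 27 and higher in 0 (median -0.027), with adjusted p 0.00179 and 0.0207, and adjusted p = 0.448 with an estimated correlation for both. Amino acid biosynthesis genes were lower in 13 of 56 cases and higher in 1 (median -0.011; adjusted p 0.0126, and adjusted p = 0.53 with an estimated correlation). Proteasome genes were lower in 2 of 33 and higher in 0 (median -0.040; adjusted p 0.0219, and adjusted p = 0.454 with an estimated correlation). The higher and lower counts adjusted over the list alone were 57 and 0 for ribosome biogenesis, 16 and 0 for the polymerases, 6 and 30 for chromosome ends, 0 and 6 for histones, 4 and 12 for nitrogen, 0 and 15 for stress, 6 and 0 for ribosomal proteins, 0 and 5 for glucose-repressed genes, 4 and 14 for amino acid biosynthesis and 0 and 0 for the proteasome. Leaving out 1 replicate ended the calls of the glucose-repressed, amino acid, ribosomal protein and proteasome lists (adjusted p up to 0.138, 0.0826, 0.294 and 0.0760), median centring those of the histone, amino acid and proteasome lists (0.0581, 0.273 and 0.771), and the scanner software's log ratio that of the ribosomal protein list (0.159). In all 763 genes differed (limma), 347 higher and 416 lower in the CAK1 strain, and 6 of them by 2-fold, all lower; at 2-fold the scanner software's log ratio gave 2 higher and 22 lower, the brightest probe 0 and 12, and uncorrected signals and the authors' values 0 and 11 each. This count was 121 (11 higher and 110 lower) with median centring, 367 without mcs6-as2 replicate 1, and 251 (74 and 177) with mcs6-as2 and the double mutant counted as 1 replicate each, a setting chosen after seeing the replicate differences given above.

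The double mutant against mcs6-as2 CAK1 compares responses that, by the labels, differ in the added cdk9-as allele. Their controls also differed in genes chosen after their values were seen: mat1-Mc (9.47 in the double mutant and 6.21, not well above background, in mcs6-as2 CAK1), mat1-Mi (6.44, above background on 2 of 4 arrays, and 8.55), mfm2 (8.92 and 6.85), ade6 (11.56 and 10.59) and tgp1 (9.76 and 8.06). The backgrounds are therefore not alike, and differences in response cannot be assigned to the cdk9-as allele alone. The ribonucleotide reductase gene cdc22 (1.54), SPBC1685.12c (1.49), adg1 (1.45), adh1 (1.34) and SPAC27D7.11c (1.30) were higher in the double mutant's response. The retrotransposon genes Tf2-2 (-2.26), Tf2-1 (-1.98) and Tf2-11 (-1.75) were lower, with log2 ratios in the double mutant of -0.14, -0.098 and 0.069. Lower as well were the phosphodiester transporter gene tgp1 (-1.79) and SPAC27D7.09c (-1.78). The largest adjusted p of these 10 genes was 3.39e-09 (limma). Glycolysis genes were higher in 13 of 16 cases and lower in 3 (median difference 0.42), and histones higher in 9 of 11 and lower in 0 (median 0.46), both with adjusted p 0.00268, and adjusted p = 0.74 with an estimated correlation. Proteasome genes were higher in 20 of 33 cases and lower in 4 (median 0.15; adjusted p 0.0444, and adjusted p = 0.752 with an estimated correlation). Ribosomal protein genes were lower in 77 of 139 and higher in 25 (median -0.16; adjusted p 0.00268, and adjusted p = 0.741 with an estimated correlation). The proteasome call was lost under every other scaling (adjusted p 0.0556 to 0.554) and without any of 3 replicates, double mutant replicate 2 (0.0649) and mcs6-as2 CAK1 replicates 1 and 2 (0.0556 and 0.0518). Adjusted over the list alone, 5 proteasome and 78 ribosomal protein genes were lower, and the other counts were the same. The responses differed for 3646 genes (limma), 1864 higher and 1782 lower, with 18 and 42 at 2-fold; median centring gave 694 and 1907, and 12 and 65 at 2-fold, and the scanner software's log ratio 77 and 122 at 2-fold.

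Against cdk9-as alone, the double mutant's response was higher for ctr4 (1.61), tgp1 (1.47), hsp16 (1.34), ctr5 (1.15) and ptl2 (1.14). It was lower for the uracil-regulated genes urg2 (-2.56) and urg1 (-1.75), and for nrg1 (-1.97), SPBC1271.07c (-1.86) and aes1 (-1.66), with a largest adjusted p of 7.27e-06 over the 10 genes (limma). Starting levels differed too, as for tgp1 (12.84 in cdk9-as and 9.76 in the double mutant) and nrg1 (7.40 and 8.63). That of urg2 (10.22 and 9.55) was lower in the double mutant, the direction of its response. Nitrogen and amino acid uptake genes were lower in 19 of 25 cases and higher in 2 (median difference -0.34), and genes on cosmids at chromosome ends lower in 52 of 89 and higher in 12 (median -0.20), both with adjusted p 7.03e-06. Heat shock genes were lower in 14 of 20 cases and higher in 3 (median -0.20; adjusted p 0.0141); for these 3 lists adjusted p = 0.369 with an estimated correlation. Mating genes were higher in 19 of 32 cases and lower in 5 (median 0.16), DNA damage and checkpoint genes higher in 27 of 50 and lower in 7 (median 0.12), and MBF targets, the genes of the G1/S transition, higher in 14 of 24 and lower in 3 (median 0.14). Adjusted p was 0.00305, 0.0232 and 0.0232, and for each adjusted p = 0.369 with an estimated correlation. Some mating genes started lower in the double mutant than in cdk9-as controls, such as ste11 (9.14 and 10.47) and mam2 (7.55 and 8.79). Others, such as fus1 (7.795 and 7.263) and tht2 (8.03 and 7.25), started higher, so the response of the mating list cannot be read apart from the starting levels. RNA polymerase I and III subunits were higher in 13 of 20 cases and lower in 0 (median 0.14), and sterol and low-oxygen genes lower in 15 of 24 and higher in 4 (median -0.17), with adjusted p 0.00483 and 0.0133, and adjusted p = 0.488 with an estimated correlation for both. Ribosome biogenesis genes were higher in 42 of 80 cases and lower in 9 (median 0.12; adjusted p 0.00286, and adjusted p = 0.568 with an estimated correlation). Amino acid biosynthesis genes were lower in 31 of 56 cases and higher in 7 (median -0.12), and proteasome genes lower in 17 of 33 and higher in 3 (median -0.094), with adjusted p 0.00231 and 0.0234, and adjusted p = 0.551 with an estimated correlation for both. Without cdk9-as replicate 1 the DNA damage, MBF and proteasome calls were lost (adjusted p 0.0758, 0.0503 and 0.136), and in the scanner software's log ratio the mating and proteasome calls (0.0634 and 0.0949), the latter also in uncorrected signals (0.0504). Adjusted over the list alone, 1 more gene passed as higher in the DNA damage, nitrogen and ribosome biogenesis lists and as lower in the amino acid biosynthesis, chromosome end, heat shock, ribosome biogenesis and sterol lists. In all 3134 genes differed (limma), 1541 higher and 1593 lower, with 7 and 21 at 2-fold; median centring gave 564 and 959, and the brightest probe of each gene 1936 and 1295. At 2-fold the scanner software's log ratio gave 36 higher and 67 lower, and the brightest probe 15 and 34. The cdk9-as arrays had a Cy3 background of 48 to 50 against 23 to 25 on the others, so for comparisons with cdk9-as the array set and the strain cannot be told apart.

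Set directly against cdk9-as, mcs6-as2 responded with higher tgp1 (3.23; log2 ratios of 2.03 and -1.20), Tf2-2 (3.16), Tf2-1 (2.94), Tf2-11 (2.91) and rtc3 (2.22). The response was lower for spd1 (-1.99), which encodes the inhibitor of ribonucleotide reductase, pan5 (-1.96), SPBC1685.12c (-1.66), aat1 (-1.54) and SPCC584.16c (-1.53). The largest adjusted p of the 10 genes was 1.97e-09 (limma). Control levels of some of these genes already differed, as for tgp1 (12.84 in cdk9-as and 8.21 in mcs6-as2) and pan5 (8.03 and 10.55). For these 2 the response cannot be read apart from the starting level. Tf2-2 (8.98 and 10.03) started higher and aat1 (12.21 and 11.39) lower in mcs6-as2, the same direction as their responses. Glycolysis genes were lower in 13 of 16 cases and higher in 0 (median difference -0.51), and respiratory chain and ATP synthase genes lower in 32 of 43 and higher in 7 (median -0.22). Adjusted p was 0.00275 and 0.0128, and for each adjusted p = 0.381 with an estimated correlation. Mating genes were higher in 22 of 32 cases and lower in 6 (median 0.40; adjusted p 0.00275, and adjusted p = 0.375 with an estimated correlation). Some of them started lower in mcs6-as2 than in cdk9-as controls, such as mfm2 (6.78 and 10.06), ste11 (8.74 and 10.47), mei2 (7.21 and 8.93) and mam2 (7.15 and 8.79). Others started higher, such as fus1 (7.89 and 7.26) and tht2 (7.86 and 7.25). The response of this list therefore cannot be read apart from the starting levels. Proteasome genes were lower in 23 of 33 cases and higher in 5 (median -0.25), and ribosomal protein genes higher in 83 of 139 and lower in 29 (median 0.15), with adjusted p 0.0247 and 0.00777, and adjusted p = 0.596 with an estimated correlation for both. The proteasome call was lost in the scanner software's log ratio (adjusted p 0.0762), the authors' values (0.0596) and uncorrected signals (0.0563), and the ribosomal protein call with median centring (0.461). Adjusted over the list alone, 84 ribosomal protein genes were higher and the other counts were the same. The test called 4080 genes (limma), 1938 higher and 2142 lower in mcs6-as2, with 62 and 58 at 2-fold; median centring gave 1963 and 1124, and 92 and 39 at 2-fold. The scanner software's log ratio gave 194 and 168 at 2-fold, and the brightest probe 117 and 74.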

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

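Tests chosen only after the results were seen were the one on near-identical Tf2 copies and the counts of probes between genes under other normalizations.

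The strains' responses differed by a test of the difference itself for 763 genes between mcs6-as2 CAK1 and mcs6-as2, 3646 between the double mutant and mcs6-as2 CAK1, 3134 between the double mutant and cdk9-as, and 4080 between mcs6-as2 and cdk9-as (limma). The log2 differences of the named genes between mcs6-as2 CAK1 and mcs6-as2 were ctr4 0.89, ctr5 0.75, SPBC887.17 0.48, nce103 0.43, mlo3 0.39, Tf2-11 -1.83, SPAC186.06 -1.74, Tf2-1 -1.72, Tf2-2 -1.57 and SPCC70.08c -1.21. Between the double mutant and mcs6-as2 CAK1 they were cdc22 1.54, SPBC1685.12c 1.49, adg1 1.45, adh1 1.34, SPAC27D7.11c 1.30, Tf2-2 -2.26, Tf2-1 -1.98, tgp1 -1.79, SPAC27D7.09c -1.78 and Tf2-11 -1.75. Between the double mutant and cdk9-as they were ctr4 1.61, tgp1 1.47, hsp16 1.34, ctr5 1.15, ptl2 1.14, urg2 -2.56, nrg1 -1.97, SPBC1271.07c -1.86, urg1 -1.75 and aes1 -1.66. Between mcs6-as2 and cdk9-as they were tgp1 3.23, Tf2-2 3.16, Tf2-1 2.94, Tf2-11 2.91, rtc3 2.22, spd1 -1.99, pan5 -1.96, SPBC1685.12c -1.66, aat1 -1.54 and SPCC584.16c -1.53.

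Among lists, the responses of mcs6-as2 CAK1 and mcs6-as2 differed by medians of -0.091 for core stress genes, 0.14 for RNA polymerase I and III, -0.011 for amino acid biosynthesis, -0.084 for chromosome ends, -0.027 for glucose-repressed genes, -0.10 for histones, -0.11 for nitrogen and amino acid uptake, -0.040 for proteasome, 0.046 for ribosomal proteins and 0.13 for ribosome biogenesis. The double mutant differed from mcs6-as2 CAK1 by medians of 0.42 for glycolysis, 0.46 for histones, 0.15 for proteasome and -0.16 for ribosomal proteins. It differed from cdk9-as by 0.12 for DNA damage, 0.14 for MBF targets, 0.14 for RNA polymerase I and III, -0.12 for amino acid biosynthesis, -0.20 for chromosome ends, -0.20 for heat shock, 0.16 for mating genes, -0.34 for nitrogen and amino acid uptake, -0.094 for proteasome, 0.12 for ribosome biogenesis and -0.17 for sterol and low-oxygen genes. The mcs6-as2 response differed from that of cdk9-as by -0.51 for glycolysis, 0.40 for mating genes, -0.25 for proteasome, -0.22 for respiratory chain and 0.15 for ribosomal proteins. All of these list differences passed with the preset correlation of 0.01, and with an estimated correlation their adjusted p ranged from 0.117 to 0.752.

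The retrotransposon genes Tf2-1, Tf2-2 and Tf2-11 rose by a median of 3.65 on the log2 scale in mcs6-as2, and the double mutant's values for them were -0.098, -0.14 and 0.069. Background correction and loess at low signal do not account for it, since the median was 3.74 in the scanner software's log ratio and 3.73 in the authors' values. The 3 values had an SD of 0.043, so 1 signal shared by all 3 copies was considered. In control cells mcs6-as2 CAK1 minus mcs6-as2 was -0.73 for Tf2-1 and -0.74 for Tf2-11 on the log2 scale, and -0.066 for Tf2-2. The widest gap was 0.67 (SE 0.079), so the 3 genes did not read as 1 signal in control RNA. A signal shared by the copies in treated RNA cannot be excluded by this, since only controls were compared. Whether some copies share a signal, as Tf2-1 and Tf2-11 may, was not tested, so how many elements changed stays open. A candidate explanation from the design is that blocking Mcs6 raises Tf2 transcripts while Cdk9 is active; it stays a hypothesis, since no strain with both alleles but without CAK1 was measured and the strains also differ in other control levels.

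Probes between genes, which the comparisons by gene do not use, were at least 2-fold higher for 1054 of 16362 tested probes in cdk9-as, 1177 in mcs6-as2, 927 in mcs6-as2 CAK1 and 1136 in the double mutant, while 239, 160, 149 and 195 were as much lower. The share at least 2-fold higher among the 3692 probes on the strand opposite to both neighbouring genes was 9.53%, 6.45%, 5.69% and 13.5% in the same order. Among the 3879 probes past 1 gene and before the next on the same strand it was 5.70%, 9.18%, 7.01% and 3.15%. This is above the opposite-strand share in mcs6-as2 and mcs6-as2 CAK1 and below it in cdk9-as and the double mutant. The share was 2.99% to 6.66% past a gene's end and 4.60% to 7.70% before a start. Differences between these shares were not tested, and the classes were not recounted under other normalizations. Of the placed probes that were 2-fold higher, 110 of 979, 105 of 1070, 64 of 852 and 72 of 1094 had a neighbouring gene on their strand that was also 2-fold higher. These totals include 352, 238, 210 and 500 probes opposite to both neighbours, which can have no such gene, so the shares are lowered by construction. Of all 5311 genes, 114, 102, 71 and 71 were called at least 2-fold higher. Whether probes and neighbours rise together was not tested. Higher and lower counts were 961 and 356, 1226 and 166, 921 and 162, and 1118 and 331 with median centring; 3204 and 1601, 3668 and 1527, 3318 and 1318, and 3539 and 1769 in the scanner software's log ratio; and 1154 and 258, 1742 and 263, 1402 and 230, and 1623 and 266 in the authors' values.

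Of 72 groups of 4 arrays examined for an array far from the rest, 4 had one, and chance marks about 1 in 20 groups, which is 3.6 here. The mcs6-as2 array replicate 4 had 88 outlier spots where the other 3 had 7 to 15. The double mutant's array replicate 2 had a median Cy5 signal of 169.9 where the others had 137.2 to 139.8. The ade6 control level was 11.49 in cdk9-as array replicate 3 and 11.5 in the others. The treated cdk9 level was 9.405 in mcs6-as2 CAK1 array replicate 1 and 9.273 to 9.282 in the others. These array levels were quantile-normalized with control spots included and outlier spots kept, so they differ slightly from the control levels given per strain.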

How the results depend on the processing

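The setting that counts mcs6-as2 and the double mutant as 1 replicate each was the only test here chosen after the results were seen. The 2-fold threshold alone left 208, 197, 146 and 165 genes in cdk9-as, mcs6-as2, mcs6-as2 CAK1 and the double mutant. It left 6, 60, 28 and 120 in the differences of mcs6-as2 CAK1 minus mcs6-as2, double mutant minus mcs6-as2 CAK1, double mutant minus cdk9-as and mcs6-as2 minus cdk9-as; fewer pass by construction. The scanner software's log ratio put 505, 495, 378 and 468 genes at 2-fold in the strains and 24, 199, 103 and 362 in the differences, with 54 higher and 83 lower in all 4 strains. For mcs6-as2 CAK1 minus mcs6-as2, median centring left 121 calls, counting mcs6-as2 and the double mutant as 1 replicate each 251, and the 2-fold count was 11 without background correction, 11 in the authors' values and 12 with the brightest probe. For the double mutant minus cdk9-as, median centring left 1523 calls. The brightest probe gave 49 genes at 2-fold there, 191 for mcs6-as2 minus cdk9-as, and 30 lower in all 4 strains. Apart from the counts of 251, which has fewer replicates, and of the 2-fold threshold, the cause was not tested.

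Leaving out each replicate gave 4258 to 4601, 3869 to 4402, 3810 to 4279 and 3971 to 4485 calls in the strains, 367 (without mcs6-as2 replicate 1) to 781, 3133 to 3687, 2420 to 3265 and 3762 to 4136 in the differences. At 2-fold the ranges were 205 to 217, 181 to 203, 141 to 162 and 165 to 170, and 5 to 7, 60 to 65, 27 to 29 and 114 to 125, with 29 to 31 higher and 19 to 21 lower genes shared by all strains. This leaves 1 sample in a strain, which is assumed to vary like the other groups. The replicate block gave 4561, 4349, 4250 and 4437 calls in the strains and 740, 3655, 3122 and 4070 in the differences, and changed no call of a named gene and 1 of 63 list calls (proteasome, double mutant minus mcs6-as2 CAK1, adjusted p 0.0502); samples with the same number in different strains deviated together with r of only -0.11 to 0.11, so they share only a number.

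Some genes reversed: with the brightest probe rpb1 read -0.10 and pch1 0.097 in cdk9-as; with median centring mcs2 read -0.015 in cdk9-as; in the scanner software's log ratio cdc18 read -0.0036, cdk9 -0.12 and mcs2 -0.014 in mcs6-as2, and cdk9 -0.083 in mcs6-as2 CAK1; the cause was not tested. Of 7592 values for 400 results of named genes under all alternatives, 7536 kept direction and side of the threshold, 39 lost the call (14 of them with a replicate left out), 10 gained it and 7 reversed; of 882 values for the 63 list calls, 787 kept them, 95 lost them and 0 reversed, and an estimated correlation ended all 63, a left-out replicate 12. The gained calls were those of cdc18, pch1 and SPAC186.06 in cdk9-as, mcs6 and cdk9 in mcs6-as2 CAK1, and Tf2-11 in the double mutant. The lost gene calls were those of cdc18, mcs6, mcs2, rpb1, csk1, fbp1, pch1, Tf2-1, cdc22, adh1, tgp1, urg1 and pan5. Signal over background limits the dim probes: only 62.0% to 76.1% of spots per channel were well above it. The authors' values give smaller ratios for dim ones than the scanner software's log ratio does. Slide and scan batch as a block was not run, since the tables used hold neither, and list tests were not run for the settings of filters, probes and array-level fits.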

Other observations

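Tests chosen only after the results were seen were those of strain differences and of median centring among the shared genes and of a missing cdk9-as allele, and the comparison of control levels.

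Before any inhibitor, the DMSO-treated strains already differed in single mating and phosphate genes, named here after their values were seen; the lists were not tested. The mating-type gene mat1-Mc stood at 9.11 in cdk9-as and 9.47 in the double mutant (normalized log2 signal, n = 2), and at 6.16 and 6.21, not well above background, in mcs6-as2 and mcs6-as2 CAK1; mat1-Mi ran the other way, at 8.19 and 8.55 in the latter and 6.47 and 6.44, above background on 2 of 4 arrays, in the former. The M-factor pheromone gene mfm2 read 10.06 in cdk9-as, 8.92 in the double mutant and 6.78 and 6.85 in the mcs6 strains, and ste11 read 10.47 in cdk9-as against 8.74 to 9.14 elsewhere. The phosphate-regulated genes tgp1 (12.84 in cdk9-as; 9.76 in the double mutant; 8.21 and 8.06 in the mcs6 strains), pho84 (14.31; 13.62; 12.97 and 13.05) and the acid phosphatase gene pho1 (14.43; 14.05; 13.34 and 12.88) were highest in cdk9-as. Other mating genes were lower in cdk9-as than in mcs6-as2 controls, such as fus1 (log2 difference -0.63), tht2 (-0.62) and sxa2 (-0.33). Further phosphate genes were higher in cdk9-as, such as vtc4 (1.15), vtc2 (1.06) and pho7 (0.43), while csk1 (-1.24) was lower. These control levels precede the log2 ratio of tgp1, which was -1.20 in cdk9-as and 2.03 in mcs6-as2. In cdk9-as controls 79 genes were at least 2-fold higher and 69 lower than the mean of the other strains (limma), against 8 and 4 in mcs6-as2, 5 and 4 in mcs6-as2 CAK1 and 3 and 1 in the double mutant; the cdk9-as arrays also had the higher Cy3 background, so strain and array set cannot be told apart here.

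The 49 genes that changed at least 2-fold in all 4 strains were weighed further, because without a wild type they may come from the compound itself. Whether these genes stayed past 2-fold was tested under other normalizations, which does not cover the size of the group. All 49 were kept in the scanner software's log ratio and in the authors' values. The former puts more genes at 2-fold in every strain, so keeping them there was a weak test. With median centring 44 of 49 were kept, so most of these calls did not rest on loess. The higher genes sod2, obr1, lsb1, sur2 and psi1 stayed called but fell below 2-fold there, each at least in the double mutant, where their log2 ratios went from 1.06, 1.12, 1.04, 1.10 and 1.13 (SE 0.025 to 0.043) to 0.78, 0.76, 0.85, 0.90 and 0.92 (SE 0.057 to 0.063), so for these the 2-fold call depends on the normalization. The measured changes were not of equal size in every strain: 31 of 49 had strain means more than 0.5 apart on the log2 scale with adjusted p under 0.05 (limma), and the median span was 0.71. This cannot exclude a compound effect alike in every strain, since the cdk9-as arrays were a set apart and control levels differed between strains. Such an effect, an action of the compound that is modified by the strain, and a response to loss of either kinase all stay open.

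The cdk9 signal was lower in cdk9-as controls than in the mean of the other strains by a log2 difference of -1.45. This lies outside the central 99% of genes, whose lower bound is -1.24, and was the 14th lowest of 5311. Quantile normalization had already removed any general offset of the cdk9-as arrays, so this rank cannot test for one. In cdk9-as controls 69 genes were at least 2-fold lower, so an effect of the array set on single genes stays open. The double mutant, labelled with the same allele, did not share the low cdk9 signal. Its log2 ratios still correlated with those of cdk9-as by 0.162 more than with those of mcs6-as2 CAK1 (0.864 against 0.702). Whether its arrays lack the allele is not settled by this. Its controls also resembled cdk9-as in mat1-Mc (9.47 and 9.11, against 6.21 in mcs6-as2 CAK1). A shared background and a shared allele therefore cannot be told apart here. A different construct of the allele in the strains is a candidate explanation that was not tested.

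Because Cdk9 acts in elongation and 3′ processing, transcription could run further past gene ends in treated cdk9-as cells. This was examined for 1963 genes whose next gene runs towards them on the other strand. The mean of the same-strand probes between the pair exceeded the gene's log2 ratio by a median of 0.0002 and 0.037 in the replicates of cdk9-as. Both lie below the 0.1 set beforehand, so no such shift was seen for these genes by this measure. Genes followed by another on the same strand were left out. The same difference was 0.11 to 0.14 in the mcs6 strains and 0.033 to 0.052 in the double mutant. It was 0.11 to 0.21 over all strains for probes before the starts of 2155 genes whose neighbour there runs away on the other strand (0.16 and 0.19 in cdk9-as). Probes that are not past a gene's end thus exceeded 0.1 too. The threshold can therefore neither show nor exclude transcription past gene ends by itself.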
